A study of Mus musculus with 8 samples.

How the data were processed

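Gene expression was measured on 8 one-colour Agilent arrays of mouse cells, each hybridised with Cy3-labelled cRNA made from 0.2 ug of total RNA. The arrays fall into 3 groups by the vector the cells received: 2 arrays for the empty vector (Empty), 3 for wild-type EBF1 (EBF1wt) and 3 for EBF1-H240A. The group and replicate number of each array were taken from the labels.

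The scanner output of each array was produced with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes. Per the file headers, the processed signal of a spot is an intensity on a linear scale after removal of a spatial trend, with a surrogate value where a spot was not significantly above background. Mean spot and local background intensities are also deposited. Per the file headers, other columns hold flags of 0 or 1 for spots well above background, saturated spots and outlier spots, and the array annotation refers to the mouse genome build mm9. The value table of the series, as deposited, holds log2 values of the same arrays that had been normalized between arrays. The scale and the normalization were inferred from the values, whose quantiles were nearly equal on all arrays, because the authors' method is not given in the sources used here. Its columns had medians between 4.90 and 4.93 and correlated with the scanner log2 values of the same array at r = 0.971 to 0.979 across probes. Its column for each array ran in the direction of the scanner values, and its centring is not stated. The table was used only as an alternative source of values.

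The processed intensities of 43379 non-control spots per array were scaled so that every array had the same 75th percentile. Scaled values under 1 were set to 1 before log2 was taken. Outlier spots were left out, and spots of the same probe were averaged, which gave 41174 probes. A probe was kept if it was well above background on at least 2 of the 8 arrays, and 25008 probes were kept. A kept probe without a value on some array, because all its spots there were outliers, was left out of the fit, which applied to 35 probes. Probe names were brought up to date with a table of reference gene names of the mouse assembly GRCm38.p6. This matched 27816 probes by accession, 5503 by symbol and 380 by an older symbol, while 7475 kept the name given in the scanner files. That table served only for names and for the order of neighbouring genes, and printed coordinates are those of mm9 in the scanner files. Each gene was represented by its kept probe with the highest mean log2 signal, giving 16310 genes, of which 10352 had 1 kept probe and 5958 had several.

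Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). All 8 arrays entered the fit with no covariate, so that the 3 groups shared a single estimate of the spread per gene. The fit had 5 residual degrees of freedom and 1.80 prior degrees of freedom. Genes at a Benjamini-Hochberg adjusted p under 0.05, over all genes tested, are called changed. Values are log2 differences with the standard error (SE) of the model. The labels do not say whether the replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. The small number of arrays limits the precision. Where every array of a group was not well above background for a gene, only a bound is given for the fold. The bright group's mean was then set against the mean, over the arrays of the dim group, of the higher of the dim probe's signal and the lowest signal among probes well above background on that array. Such folds are written as "at least N-fold". They hold for the main processing of the values and are no minimum over the alternatives.

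The lists, tests and rules for naming genes, and the alternatives unless said otherwise, were fixed before the data were examined. The 19 gene lists cover pre-B cell receptor and B cell signalling genes, B-lineage transcription factors, V(D)J recombination, other B-lineage surface and target genes, T and innate lymphoid cell genes, Notch response genes, myeloid, erythroid, megakaryocyte and mast cell genes, dendritic cell and MHC class II genes, stem and multipotent progenitor genes, stromal feeder cell genes, hepatocyte genes, cell cycle genes, genes of the IL-7, STAT5 and MYC axis, interferon response genes, CCR4-NOT and mRNA decay genes, immediate early and stress genes, and p53 and apoptosis genes. No measured gene was in more than 1 list. Each list was tested with limma's camera (two-sided, inter-gene correlation preset to 0.01), adjusted over the 19 lists within a comparison, and again with an estimated correlation. Members were also counted after adjustment over the list alone. In each of the 3 comparisons the text names the 8 called genes with the largest increase and the 8 with the largest decrease, skipping unnamed and predicted models and antigen receptor segments. It also names the 3 members with the smallest adjusted p of each called list, and always Ebf1, Cnot3, Cd79a, Cd79b, Vpreb1, Igll1, Pax5, Blk and Pou2af1. A further gene chosen in advance is not reported here, though it stays in the fits and in the counts of genes and list members. Further members are named as examples, mostly those with the largest changes of their list, and were chosen after their values were seen.

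Both comparisons with Empty use the same 2 control arrays. Correlation, covariance and agreement in sign between them were therefore set beside values from 100 simulations of unchanged groups against those controls. Counts of shared calls were set beside those of independent lists, which do not allow for the shared controls. The scanner files place the arrays on 2 slides, each scanned as a batch of its own. Slide 1 held Empty 1, EBF1wt 2, EBF1-H240A 1 and EBF1-H240A 2, and slide 2 held Empty 2, EBF1wt 1, EBF1wt 3 and EBF1-H240A 3. Each slide held all 3 groups, so results were also computed with the slide as a block and, as alternatives chosen after seeing the data, within each slide and, for the correlation of fold changes, with a separate Empty array for each protein. The other alternatives were quantile normalization, normexp background correction with an offset of 50, no filter on dim probes, a filter that asks for signal well above background on all 8 arrays, the mean over the probes of a gene, a variance trend with robust eBayes, only the arrays of the groups compared, the replicate number as a block, the series value table, a threshold of 0.01, and leaving out each array in turn.

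The procedure was tested on simulated data built on the 16310 genes, with 50 genes changed at each of 4 fold sizes. For EBF1wt against Empty, 50% of genes changed 1.5-fold and 84% of those changed 2-fold were called in the right direction, and 4.17% of calls were wrong. For EBF1-H240A against Empty the shares were 54% and 70%, with 5.45% of calls wrong. For EBF1-H240A against EBF1wt they were 54% and 84%, with 5.20% wrong. The simulations changed fewer genes than were called in the data and drew the noise of each gene independently. These shares may therefore differ from those of the fits to the data. Tables were read with data.table, version 1.17.8, and the plots were drawn with matplotlib 3.10.9 in Python 3.11.15.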

Results

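EBF1 is a transcription factor required for the B-lymphocyte programme, and cells that lack it stop before B-lineage commitment. Ebf1-deficient c-Kit-positive progenitors from mouse fetal liver were grown on OP9 cells, a mouse bone marrow stromal line that supports lymphoid development. The medium held 5 ng/ml interleukin 7, 10 ng/ml Flt3 ligand and 10 ng/ml stem cell factor. The cells received a retrovirus that carried GFP alone (Empty, n = 2 arrays), GFP with wild-type EBF1 (EBF1wt, n = 3) or GFP with EBF1-H240A (n = 3), in which an alanine replaces a histidine. GFP-positive cells were sorted 36 h later and their RNA was profiled on arrays. The design asks which genes EBF1 changes in these progenitors and which of those changes differ with EBF1-H240A. That substitution is known to impair the contact of EBF1 with CNOT3, a subunit of the CCR4-NOT complex, which shortens mRNA tails and takes part in transcriptional control.

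Between 54.6% and 59.7% of probes were well above background on each array, and none (0) of the spots was saturated. The 75th percentile of the processed intensity ranged from 232 on EBF1-H240A 3 to 326 on Empty 2 before scaling. Arrays of the same group correlated at r = 0.991 to 0.995 across genes, although genes are not independent replicates. The first principal component held 63.8% of the variance and placed both Empty arrays (-75.4 and -75.1) apart from the 6 arrays with EBF1, which lay between 18.0 and 31.7.

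The Ebf1 probe lies at 44818365 to 44818424 on chromosome 11 of mm9. Its log2 signal was 10.11 and 10.19 on the Empty arrays, 10.19, 10.18 and 10.20 with EBF1wt, and 10.44, 10.34 and 10.16 with EBF1-H240A. Neither protein was accompanied by a called change of this signal (0.03 ± 0.09 SE, adjusted p = 0.805 with EBF1wt, and 0.16 ± 0.09, adjusted p = 0.191 with EBF1-H240A). Without EBF1-H240A 3 the second difference was 0.24 and was called (adjusted p = 0.0445), and without Empty 1 the first was -0.01 (adjusted p = 0.969). This signal is therefore used here neither to check the labels nor to compare the amounts of the introduced proteins.

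**Figure D1:**
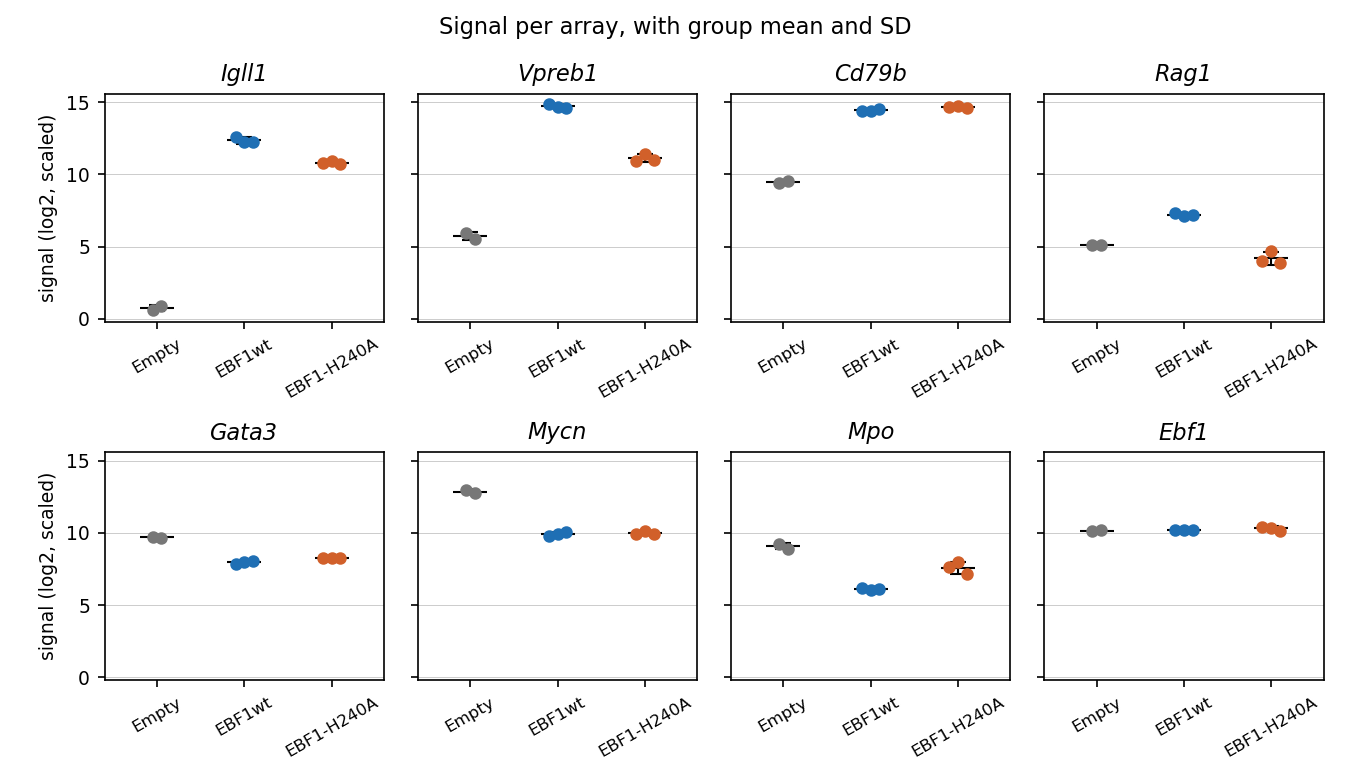
Log2 scaled signal (y axis) of Igll1, Vpreb1, Cd79b, Rag1, Gata3, Mycn, Mpo and Ebf1 in the 3 groups (x axis), with a point per array, a bar at the group mean and error bars of 1 SD. Vpreb1 averaged 5.73 with Empty, 14.72 with EBF1wt and 11.11 with EBF1-H240A, while Cd79b averaged 9.49, 14.43 and 14.65.

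EBF1wt against Empty asks what wild-type EBF1 changes. With EBF1wt, the genes of the surrogate light chain, which pairs with the immunoglobulin heavy chain in the pre-B cell receptor, rose from low or undetected levels. Igll1 was not well above background on either Empty array and rose at least 933-fold (adjusted p = 1.99e-07), and Vpreb1 rose 507-fold, by 8.98 ± 0.19 on the log2 scale (SE, n = 3 and 2, adjusted p = 9.67e-07). The Igll1 fold is that of the brighter of its 2 probes. The other Igll1 probe rose less, with mean log2 signals of 0.70 with Empty, 5.56 with EBF1wt and 3.70 with EBF1-H240A. Cd79b, a signalling subunit of the B cell receptor, rose 30.7-fold (4.94 ± 0.08, adjusted p = 5.34e-07). The mast cell protease gene Cpa3 fell by 3.52 ± 0.22 on the log2 scale (adjusted p = 5.21e-05), and Gata3, a transcription factor of T and innate lymphoid cells, fell by 1.74 ± 0.07 (adjusted p = 8.23e-06). In mm9 the brighter Igll1 probe lies at 16861104 to 16861163 and the Vpreb1 probe at 16868559 to 16868618 on chromosome 16, and the Cd79b probe at 106172780 to 106172839 on chromosome 11.

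Among 16310 genes tested, 6264 changed, 2798 of them higher and 3466 lower with EBF1wt. Without Empty 1 the balance turned to 2203 higher and 1990 lower, and within slides 1 and 2 it was 122 and 11, and 339 and 59. Of the called genes, 925 rose and 457 fell at least 2-fold by their fitted change, and 817 and 426 with undetected groups at their bound, where 34 genes rose at least 32-fold. The largest fitted increases also held genes outside the lists. Genes given with a bound were not well above background in 1 of the groups, so that their rank is not established. Outside the lists were the collagen gene Col26a1 (at least 562-fold), the troponin gene Tnnt2 (at least 183-fold), the renin genes Ren1 (at least 278-fold) and Ren2 (at least 127-fold), Stum (at least 118-fold) and the lactase gene Lct (451-fold, 8.82 ± 0.24). Ren1 and Ren2 are near-identical paralogs, as are Vpreb1 and Vpreb2, and probes may not separate them. The largest measured decreases after Cpa3 were those of Tmem158 (-3.31 ± 0.17), Slc35d3 (-3.28 ± 0.13), the integrin gene Itgae (-3.23 ± 0.10) and the globin gene Hbb-bt (-3.13 ± 0.08), which has close paralogs. Ampd1 (at least 4.87-fold lower), Il20ra (at least 3.19-fold) and Casq2 (at least 5.05-fold) were undetected with EBF1wt.

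Of the 20 measured pre-B cell receptor and B cell signalling genes, 14 rose, none (0) fell and 6 did not pass. Adjusted over the list alone, 14 rose and 1 fell. The list was higher than other genes (median log2 difference 0.86, camera adjusted p = 2.34e-07) and kept its call with an estimated correlation (adjusted p = 0.0299 with an estimated correlation). Beyond the genes already named, Vpreb2 rose by 7.69 ± 0.25, the inhibitory receptor gene Cd22 by 2.49 ± 0.13 and the kinase gene Blk by 0.82 ± 0.13 (adjusted p = 0.00312). Cd79a rose by 0.91 ± 0.24 (adjusted p = 0.0247), a call that was lost without Empty 1 (0.57, adjusted p = 0.140). With normexp background correction Cd79a and Blk, both dim on these arrays, no longer passed (adjusted p = 0.276 and 0.0895).

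Other B-lineage surface and target genes were higher as a list too: 10 of 18 rose, 4 fell and 4 did not pass, with the counts of 10 and 4 when adjusted over the list alone (median 0.56, camera adjusted p = 0.00415; adjusted p = 0.170 with an estimated correlation). Cd40 rose by 3.41 ± 0.12, Ms4a1 (CD20) at least 28.1-fold and the low-affinity IgE receptor gene Fcer2a at least 14.8-fold, while Fcmr (-2.56 ± 0.15) and Cxcr5 (-1.73 ± 0.14) fell. When only probes well above background on all arrays were kept, this list lost its call (adjusted p = 0.0805). Of 15 B-lineage transcription factors, 7 rose, 4 fell and 4 did not pass, the same counts of 7 and 4 adjusted over the list alone (median 0.23, camera adjusted p = 0.196). Pou2f2 (1.86 ± 0.07), Spib (1.84 ± 0.09) and Pou2af1 (1.74 ± 0.20, adjusted p = 0.000746) rose and Lef1 fell by 2.55 ± 0.14. Pax5 was not well above background on any array (0 of 8) and was not tested. Of 11 V(D)J recombination genes, 4 rose, 3 fell and 4 did not pass, with 4 and 3 adjusted over the list alone. Their median was -0.23 (-0.11 without EBF1wt 3), their mean 0.13 and the camera direction upward (adjusted p = 0.954), and Rag1, which encodes a subunit of the recombinase, rose by 2.10 ± 0.24.

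Genes of T and innate lymphoid cells were lower with EBF1wt: 10 of 19 fell, 2 rose and 7 did not pass, and 11 fell and 2 rose adjusted over the list alone (median -0.28, camera adjusted p = 0.00415; adjusted p = 0.170 with an estimated correlation). Cd5 (-2.27 ± 0.15), Cd3g (-1.77 ± 0.10) and Il2rb (-1.62 ± 0.10) fell, while Notch1 rose by 1.29 ± 0.11. Of 6 measured Notch response genes 5 rose and 1 did not pass, also adjusted over the list alone (median 1.97, camera adjusted p = 0.000203; adjusted p = 0.170 with an estimated correlation). Heyl rose at least 10.4-fold, Dtx1 by 3.11 ± 0.16 and Notch3 by 2.40 ± 0.12. Of 19 stem and multipotent progenitor genes 10 fell, 5 rose and 4 did not pass, with 11 lower and 5 higher adjusted over the list alone (median -0.51, camera adjusted p = 0.0423; adjusted p = 0.201 with an estimated correlation). Mycn (-2.94 ± 0.12) and the surface marker gene Cd34 (-1.93 ± 0.10) fell, while Lmo2 rose by 1.15 ± 0.07. The stem and progenitor call was lost without Empty 2 (adjusted p = 0.0806), without EBF1wt 1 (0.0638) and without EBF1wt 3 (0.0696).

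Cell cycle genes were lower with EBF1wt, 19 of 30 having fallen, 2 risen and 9 not passed, with 21 and 2 adjusted over the list alone (median -0.40, camera adjusted p = 6.45e-05; adjusted p = 0.402 with an estimated correlation). Ccne1 fell by 0.76 ± 0.09, whereas the D-type cyclin genes Ccnd1 (1.41 ± 0.08) and Ccnd3 (0.77 ± 0.07) rose. Another D-type cyclin gene, Ccnd2, was lower, with log2 signals of 13.27 and 13.19 with Empty and 12.87, 12.89 and 12.78 with EBF1wt. Of 21 interferon response genes 17 rose, none (0) fell and 4 did not pass, and 19 rose and 1 fell adjusted over the list alone (median 0.54, camera adjusted p = 4.32e-06; adjusted p = 0.442 with an estimated correlation). Ifit3 rose by 2.03 ± 0.19, Ifit1 by 1.58 ± 0.15 and Rsad2 by 1.41 ± 0.16. Of 22 immediate early and stress genes 14 rose, 1 fell and 7 did not pass, with 16 and 1 adjusted over the list alone (median 0.78, camera adjusted p = 1.60e-05; adjusted p = 0.284 with an estimated correlation). The heat shock genes Hspa1a (3.17 ± 0.12) and Hspa1b (3.06 ± 0.14), which are paralogs, and the phosphatase gene Dusp2 (2.72 ± 0.08) rose.

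Genes typical of stromal cells, the kind of cell in the OP9 feeder layer, were also higher in the EBF1wt samples. Of 19 measured members 6 rose, none (0) fell and 13 did not pass, with 5 and 0 adjusted over the list alone (median 0.59, camera adjusted p = 0.00182; adjusted p = 0.417 with an estimated correlation). Pdgfrb rose by 1.54 ± 0.09, Timp3 by 0.84 ± 0.13 and Cxcl12 by 0.59 ± 0.10, next to the increases of the B-lineage, Notch response, interferon and stress lists. The stromal median was 0.10 within slide 1, with 1 EBF1wt and 1 Empty array, and 0.87 within slide 2. On EBF1wt 3 the members had a median signal of 6.22, against 5.53 and 5.37 on EBF1wt 1 and 2, and without that array the median difference was 0.39, with the list still called.

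The remaining lists were not called for EBF1wt against Empty. Their members rose, fell and did not pass as follows: myeloid genes 7, 7 and 11 (9 and 7 adjusted over the list alone, adjusted p = 0.726) and erythroid genes 3, 5 and 3 (3 and 5, adjusted p = 0.876). For megakaryocyte and mast cell genes the counts were 3, 3 and 4 (3 and 3 adjusted over the list alone, adjusted p = 0.773), and for dendritic cell and MHC class II genes 4, 6 and 6 (4 and 6, adjusted p = 0.503). Hepatocyte genes, markers of another fetal liver cell type, had 0 members that rose, 2 that fell and 2 that did not pass (0 and 2 adjusted over the list alone, adjusted p = 0.136). For the IL-7, STAT5 and MYC axis the counts were 7, 8 and 7 (8 and 8 adjusted over the list alone, adjusted p = 0.737), for CCR4-NOT and mRNA decay 5, 5 and 15 (5 and 5, adjusted p = 0.529), and for p53 and apoptosis 4, 5 and 7 (4 and 6, adjusted p = 0.761). Large single changes within them were those of the granule enzyme gene Mpo (-2.95 ± 0.23), Alas2 (at least 43.6-fold higher), Nfe2 (2.39 ± 0.10), Itga2b (-2.74 ± 0.26), Vwf (2.91 ± 0.25), Itgax (-2.16 ± 0.18), Cish (1.74 ± 0.07) and Perp (-2.34 ± 0.14). Il7r, the receptor chain for interleukin 7, fell by 1.09 ± 0.08. Cnot3 itself fell by 0.39 ± 0.08 (adjusted p = 0.00983), but only 2 of its 3 probes had that sign, and the call was lost with the mean over probes (-0.24, adjusted p = 0.106) and without Empty 1 (-0.38, adjusted p = 0.0559). Median and mean had opposite signs for myeloid genes (-0.02 and 0.01) and erythroid genes (-0.29 and 0.52), and for megakaryocyte and mast cell genes the test pointed up with a mean of -0.01.

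With the slide as a block 5785 genes were called for EBF1wt against Empty, and 133 within slide 1 and 398 within slide 2 alone, where 4318 and 3951 genes had an unadjusted p under 0.05. Each slide holds 1 Empty array and only 1 group with 2 arrays, EBF1-H240A in slide 1 and EBF1wt in slide 2, so that fits within a slide take the spread from that group alone (1 residual degree of freedom). All 6264 called genes had the same sign within both slides, although they were chosen on these same arrays. Within slides 1 and 2 the list medians were 0.59 and 0.74 for pre-B cell receptor and B cell signalling genes, 0.76 and 0.77 for other B-lineage genes, -0.34 and -0.28 for T and innate lymphoid cell genes, and 1.76 and 2.16 for Notch response genes. They were -0.43 and -0.54 for stem and progenitor genes, -0.46 and -0.36 for cell cycle genes, 0.78 and 0.41 for interferon response genes and 0.99 and 0.60 for immediate early and stress genes. With the slide as a block the camera test called the same number of lists, 9, with adjusted p = 5.07e-07 for the pre-B cell receptor list, 0.0445 for stem and progenitor genes and 0.00216 for stromal genes.

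EBF1-H240A against Empty asks the same for the altered protein. With EBF1-H240A the surrogate light chain genes rose as well: Igll1 at least 319-fold at the brighter of its 2 probes (adjusted p = 3.38e-07) and Vpreb1 41.6-fold (5.38 ± 0.19, n = 3 and 2, adjusted p = 4.40e-06). The other Igll1 probe rose less. Cd79b rose 35.9-fold (5.17 ± 0.08, adjusted p = 3.38e-07). Rag1 fell by 0.92 ± 0.24, the opposite of its rise with EBF1wt. Lat and Lck, which act in T cell receptor signalling, fell (-2.08 ± 0.10 and -1.34 ± 0.08).

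In total 7272 genes changed, 3516 higher and 3756 lower with EBF1-H240A. Without Empty 1 the balance turned to 2844 higher and 2580 lower, and within slides 1 and 2 it was 766 and 335, and 275 and 47. By their fitted change 1083 rose and 556 fell at least 2-fold, and 945 and 533 with undetected groups at their bound. The largest fitted increases, where those with a bound have no established rank, were those of Col26a1 (at least 625-fold), Ren1 (at least 728-fold), Igll1, Ren2 (at least 343-fold), Lct (908-fold, 9.83 ± 0.24), the ficolin gene Fcnb (at least 106-fold), Tmprss6 (376-fold, 8.55 ± 0.13) and Cidea (at least 78.1-fold). The largest measured decreases were those of Cpa3 (-3.74 ± 0.22), Hbb-bt (-3.58 ± 0.08), Calml3 (-3.52 ± 0.17), Tmem158 (-3.44 ± 0.17) and the fetal liver glycoprotein gene Ahsg (-3.37 ± 0.09). Il20ra (at least 3.66-fold lower), Ampd1 (at least 5.58-fold) and Megf10 (at least 4.86-fold) were undetected with EBF1-H240A. The Il20ra call was lost with normexp background correction (-0.27, adjusted p = 0.0624). With the slide as a block 6919 genes were called, and within slides 1 and 2 alone 1101 and 322.

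Of 20 pre-B cell receptor and B cell signalling genes, 14 rose, 2 fell and 4 did not pass with EBF1-H240A, and 16 rose and 2 fell adjusted over the list alone (median 0.65, camera adjusted p = 1.64e-05; adjusted p = 0.0698 with an estimated correlation). Cd22 rose by 2.72 ± 0.13 and Vpreb2 by 4.13 ± 0.25, while Cd24a fell by 0.96 ± 0.14. Cd79a rose by 0.87 ± 0.24 (adjusted p = 0.0246), which no longer passed without Empty 1 (0.54, adjusted p = 0.143), without EBF1-H240A 1 (0.91, adjusted p = 0.0505), without EBF1-H240A 2 (0.84, adjusted p = 0.0646) or without EBF1-H240A 3 (0.87, adjusted p = 0.0598). Blk (0.24 ± 0.13, adjusted p = 0.175) and Pou2af1 (0.56 ± 0.20, adjusted p = 0.0560) did not pass, though Pou2af1 was called with the slide as a block (0.62, adjusted p = 0.0122) and without EBF1-H240A 1 (0.74, adjusted p = 0.0145). Other B-lineage surface and target genes numbered 9 higher, 5 lower and 4 not passing of 18, with 9 and 5 adjusted over the list alone (median 0.47, camera adjusted p = 0.0616). Ms4a1 rose at least 66.9-fold and Cd40 by 3.41 ± 0.12. B-lineage transcription factors had 5 members that rose, 4 that fell and 6 that did not pass (7 and 5 adjusted over the list alone, camera adjusted p = 0.795), and V(D)J recombination genes 3, 5 and 3 (3 and 6 adjusted over the list alone, camera adjusted p = 0.463).

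T and innate lymphoid cell genes were lower as a list, with 9 of 19 fallen, 2 risen and 8 not passed, and 9 and 2 adjusted over the list alone (median -0.43, camera adjusted p = 0.00219; adjusted p = 0.135 with an estimated correlation), Gata3 having fallen by 1.42 ± 0.07. Of 6 Notch response genes 4 rose and 2 did not pass, and 5 rose and 1 fell adjusted over the list alone (median 1.80, camera adjusted p = 0.00510; adjusted p = 0.258 with an estimated correlation). Heyl rose at least 42.1-fold, Dtx1 by 3.42 ± 0.16 and Notch3 by 2.49 ± 0.12, and the list's call was lost when only probes well above background on all arrays were kept (adjusted p = 0.104). Stem and multipotent progenitor genes fell in 13 of 19 cases, rose in 3 and did not pass in 3, with the same 13 and 3 adjusted over the list alone (median -0.58, camera adjusted p = 0.00552; adjusted p = 0.135 with an estimated correlation). Mycn (-2.88 ± 0.12) and Gfi1b (-2.34 ± 0.17) fell, and Lmo2 rose by 1.68 ± 0.07.

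Cell cycle genes fell in 28 of 30 cases, and the other 2, Ccnd1 (1.85 ± 0.08) and Ccnd3 (0.30 ± 0.07), rose, with 28 and 2 adjusted over the list alone (median -0.62, camera adjusted p = 7.00e-08; adjusted p = 0.258 with an estimated correlation). The replication genes Cdc6 (-0.92 ± 0.08) and Mcm5 (-0.90 ± 0.08) were among those that fell. Interferon response genes rose in 19 of 21 cases and did not pass in 2, with 20 higher and 1 lower adjusted over the list alone (median 0.63, camera adjusted p = 1.17e-05; adjusted p = 0.472 with an estimated correlation), Ifit3 by 2.18 ± 0.19, Ifit1 by 1.86 ± 0.15 and Rsad2 by 1.34 ± 0.16. Immediate early and stress genes rose in 12 of 22 cases, fell in 1 and did not pass in 9, with 12 and 1 adjusted over the list alone (median 0.42, camera adjusted p = 0.00453; adjusted p = 0.472 with an estimated correlation), Hspa1a by 2.77 ± 0.12, Hspa1b by 2.64 ± 0.14 and Dusp2 by 2.59 ± 0.08. Stromal genes rose in 8 of 19 cases and did not pass in 11, with 8 and 0 adjusted over the list alone (median 0.58, camera adjusted p = 0.00453; adjusted p = 0.472 with an estimated correlation). Pdgfrb rose by 1.95 ± 0.09, Col1a1 by 1.16 ± 0.19 and Timp3 by 0.87 ± 0.13, and the stromal median was 0.47 within slide 1 and 0.78 within slide 2. For the other called lists the medians within slides 1 and 2 were 0.69 and 0.64 (pre-B cell receptor and B cell signalling), -0.42 and -0.76 (T and innate lymphoid cells), 1.67 and 2.05 (Notch response), -0.51 and -0.55 (stem and progenitor), -0.70 and -0.52 (cell cycle), 0.78 and 0.54 (interferon response) and 0.64 and 0.25 (immediate early and stress). With the slide as a block 8 lists were called, with adjusted p = 2.68e-05 for the pre-B cell receptor list and 1.62e-07 for cell cycle genes.

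Lists without a call for EBF1-H240A against Empty included the myeloid genes, of which 16 rose, 7 fell and 2 did not pass (16 and 8 adjusted over the list alone, median 0.54, adjusted p = 0.0610). Cebpb rose by 2.23 ± 0.09, Csf2rb by 2.10 ± 0.17 and Prtn3 by 2.04 ± 0.10, while Mpo fell by 1.49 ± 0.23. Counts of members that rose, fell and did not pass were 3, 5 and 3 for erythroid genes (3 and 6 adjusted over the list alone, adjusted p = 0.892) and 5, 3 and 2 for megakaryocyte and mast cell genes (5 and 3, adjusted p = 0.791). They were 5, 7 and 4 for dendritic cell and MHC class II genes (5 and 7 adjusted over the list alone, adjusted p = 0.501) and 1, 3 and 0 for hepatocyte genes (1 and 3, adjusted p = 0.116). Further counts were 10, 8 and 4 for the IL-7, STAT5 and MYC axis (10 and 10 adjusted over the list alone, adjusted p = 0.904), 8, 5 and 12 for CCR4-NOT and mRNA decay genes (8 and 5, adjusted p = 0.795) and 5, 4 and 7 for p53 and apoptosis genes (5 and 4, adjusted p = 0.795). Il7r fell by 1.45 ± 0.08. Cnot3 fell by 0.34 ± 0.08 (adjusted p = 0.0157), with 2 of its 3 probes of that sign, and lost its call without Empty 1 (-0.32, adjusted p = 0.0754), without Empty 2 (-0.35, adjusted p = 0.0626) and with the mean over its probes (-0.20, adjusted p = 0.156). Median and mean differed in sign for erythroid genes (-0.51 and 0.34), the IL-7, STAT5 and MYC axis (0.07 and -0.02) and CCR4-NOT genes (-0.06 and 0.11), and the erythroid median was -0.15 with undetected genes at their bound.

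EBF1-H240A against EBF1wt tests the difference between the proteins directly. Single genes of the surrogate light chain and of the recombinase were lower with EBF1-H240A, while the lists that hold them were not called (camera adjusted p = 0.0986 and 0.218). Vpreb1 was 12.2-fold lower (-3.60 ± 0.17 on the log2 scale, SE, n = 3 and 3, adjusted p = 0.000609), Vpreb2 11.7-fold (-3.55 ± 0.22, adjusted p = 0.000994) and Rag1 8.11-fold, with the same sign at all 3 probes (-3.02 ± 0.22, adjusted p = 0.00135). Igll1 was lower as well (-1.55 ± 0.14, adjusted p = 0.00296). Cd79b did not pass (0.23 ± 0.08, adjusted p = 0.138). Myeloid genes were higher as a list, with 8 of 25 members called and the list's call lost with an estimated correlation (adjusted p = 0.321 with an estimated correlation). Among those called were S100a9, a granulocyte calcium-binding protein gene (at least 7.39-fold, adjusted p = 0.0152), Mpo (1.47 ± 0.20, adjusted p = 0.0117) and the transcription factor gene Cebpb (0.63 ± 0.08, adjusted p = 0.00888). Within slides 1 and 2 the difference was -3.48 and -3.78 for Vpreb1, -2.75 and -3.42 for Rag1, -1.35 and -1.72 for Igll1 and 1.79 and 0.98 for Mpo.

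The 2 proteins differed at 1038 of 16310 genes, 594 higher and 444 lower with EBF1-H240A, and 108 and 68 of these by at least 2-fold in fitted change (88 and 63 with undetected groups at their bound). The largest measured increases were those of Ramp3 (3.78 ± 0.15), the steroid reductase gene Srd5a2 (3.62 ± 0.56, adjusted p = 0.0156), the acute-phase gene Orm1 (3.51 ± 0.32), which has close paralogs, Grifin (3.33 ± 0.22), Col16a1 (3.28 ± 0.19) and Kcne1 (3.05 ± 0.44). S100a9 and Klra2 (at least 3.87-fold higher) were undetected with EBF1wt. Besides Vpreb1, Vpreb2 and Rag1 the largest measured decreases were those of Evpl (-3.35 ± 0.19), Scgb1c1 (-2.94 ± 0.14), Htra3 (-2.30 ± 0.16) and Mc1r (-2.29 ± 0.24), and Aldh1a3 (at least 3.22-fold lower) was undetected with EBF1-H240A. Calls were lost for S100a9 without EBF1wt 1 (3.92, adjusted p = 0.0582), for Srd5a2 without EBF1wt 1 (adjusted p = 0.0597), EBF1-H240A 1 (0.0564) or EBF1-H240A 3 (0.0597), for Kcne1 without EBF1-H240A 3 (0.0511) and for Klra2 without EBF1-H240A 1 (0.0545) or EBF1-H240A 3 (0.0511). The count of 1038 was 365, 441 and 683 without EBF1wt 1, 2 and 3, and 448 and 449 without EBF1-H240A 1 and 3. With the slide as a block 646 genes were called, and in limma fits within slide 1 and within slide 2 none (0) were, where 1526 and 1600 genes had an unadjusted p under 0.05 and all 1038 genes had the same sign within both slides, although they too were chosen on these same arrays.

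Of 20 pre-B cell receptor and B cell signalling genes, 2 were higher, 5 lower and 13 not called. Adjusted over the list alone, 5 were higher and 6 lower (median -0.07, but -0.14 without EBF1wt 3 and -0.04 without EBF1-H240A 2, camera adjusted p = 0.0986). Syk was higher (0.41 ± 0.08) and Cd24a lower (-0.95 ± 0.13). Blk was lower (-0.57 ± 0.12, adjusted p = 0.0366). Its call was lost in 7 of the 8 fits that left out an array, all but that without EBF1wt 2 (adjusted p = 0.0629 to 0.127), and with the slide as a block (-0.55, adjusted p = 0.0786). Cd79a (-0.03 ± 0.22, adjusted p = 0.948) did not pass. B-lineage transcription factors had 2 lower members and 13 not called (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0532), and Pou2af1, a coactivator of octamer-binding factors, was lower (-1.18 ± 0.18, adjusted p = 0.0146). That call was lost without EBF1wt 1 (-1.11, adjusted p = 0.0614) and with normexp background correction (-0.26, adjusted p = 0.232). V(D)J recombination genes had 1 lower member, Rag1, and 10 not called (1 and 2 adjusted over the list alone, camera adjusted p = 0.218). Other B-lineage surface and target genes had 1 higher, 4 lower and 13 not called (3 and 6 adjusted over the list alone, camera adjusted p = 0.0648), with Tnfrsf13c (-0.83 ± 0.10), Ly6d (-0.82 ± 0.06) and Il2ra (-0.63 ± 0.07) lower and Ms4a1 higher by 1.25 ± 0.25.

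Myeloid genes were higher with EBF1-H240A than with EBF1wt: 8 of 25 rose, none (0) fell and 17 did not pass, and 13 rose and 1 fell adjusted over the list alone (median 0.40, camera adjusted p = 2.94e-07; adjusted p = 0.321 with an estimated correlation). Cebpd (0.89 ± 0.17), the lysozyme gene Lyz1 (0.71 ± 0.16) and the cytokine receptor gene Csf2rb (0.66 ± 0.15) were higher. The list's median was 0.28 within slide 1 and 0.52 within slide 2, and the stromal list had a median of 0.03 (0.34 within slide 1 and 0.03 within slide 2, 1 of 19 called higher and 18 not, 1 and 0 adjusted over the list alone, camera adjusted p = 0.774). Cell cycle genes were lower: 5 of 30 fell, 1 rose and 24 did not pass, and 17 fell and 1 rose adjusted over the list alone (median -0.24, -0.28 within slide 1 and -0.19 within slide 2, camera adjusted p = 7.45e-11; adjusted p = 0.321 with an estimated correlation). Ccnd3 (-0.47 ± 0.06, adjusted p = 0.00991), Mcm5 (-0.41 ± 0.07, adjusted p = 0.0209) and Top2a (-0.41 ± 0.08) were lower and Ccnd1 was higher (0.44 ± 0.07, adjusted p = 0.0189). The Ccnd1 call was lost without EBF1wt 1, 2 or 3 (adjusted p = 0.0731, 0.0614 and 0.0542) and without EBF1-H240A 1 (0.0507). Mcm5 lost its call without EBF1wt 1, 2 or 3 (adjusted p = 0.0809, 0.0667 and 0.0507), without EBF1-H240A 1 or 2 (0.0793 and 0.0576) and with the slide as a block (0.0540).

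In other splits of the same 6 arrays into groups of 3 the camera test called up to 5 lists, and of the 9 other splits 4 called the myeloid list (lowest adjusted p = 1.86e-07, below the 2.94e-07 of the real split) and 6 the cell cycle list (lowest 6.58e-07). The 2 called lists became 5 called without EBF1wt 1 and 4 without EBF1-H240A 1, and 2 lists were called with the slide as a block (adjusted p = 1.70e-07 for myeloid and 7.67e-10 for cell cycle genes). The remaining 17 lists were not called for this comparison. T and innate lymphoid cell genes had 3 higher, 4 lower and 12 not called (3 and 5 adjusted over the list alone, adjusted p = 0.502), with Zap70 lower (-1.18 ± 0.16) and Id2 higher (0.44 ± 0.08), and Notch response genes 1, 0 and 5 (1 and 2, adjusted p = 0.95), with Heyl higher by 2.01 ± 0.22. The same counts for erythroid genes were 0, 1 and 10 (0 and 1 adjusted over the list alone, adjusted p = 0.244), and for megakaryocyte and mast cell genes 0, 0 and 10 by limma (1 and 1, with 2 at an unadjusted p under 0.05, adjusted p = 0.99). Those of dendritic cell and MHC class II genes were 0, 1 and 15 (0 and 1 adjusted over the list alone, adjusted p = 0.936), of stem and progenitor genes 3, 1 and 15 (3 and 4, adjusted p = 0.423) and of hepatocyte genes 1, 1 and 2 (1 and 2, adjusted p = 0.265). Cd34 was higher by 0.75 ± 0.09 and Ahsg lower (-1.69 ± 0.08). The IL-7, STAT5 and MYC axis had 0, 2 and 20 (3 and 6 adjusted over the list alone, adjusted p = 0.130), immediate early and stress genes 1, 0 and 21 (3 and 6, adjusted p = 0.0648) and p53 and apoptosis genes 2, 2 and 12 (3 and 2, adjusted p = 0.936). Of 21 interferon response genes limma called 0, also adjusted over the list alone, and 0 had an unadjusted p under 0.05 (median 0.08, adjusted p = 0.315). Of the 25 CCR4-NOT and mRNA decay genes limma called 0, also adjusted over the list alone, while 6 had an unadjusted p under 0.05 (median 0.01, adjusted p = 0.936). Cnot3 differed by 0.06 ± 0.07 (adjusted p = 0.701) and Ebf1 by 0.13 ± 0.08 (adjusted p = 0.415). Median and mean had opposite signs for T and innate lymphoid cell genes (0.03 and -0.13), Notch response genes (-0.09 and 0.20) and dendritic cell genes (0.01 and -0.05). For Notch response genes and for megakaryocyte and mast cell genes (median 0.12, mean 0.05) the test pointed down, as it did for CCR4-NOT genes with a median of 0.01 and a mean of 5.93e-05. Several medians near 0, in lists without a call, moved by over 1.5 times or changed sign without single arrays, for example from 0.03 to 0.23 for stromal genes without EBF1wt 3.

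**Figure D2:**
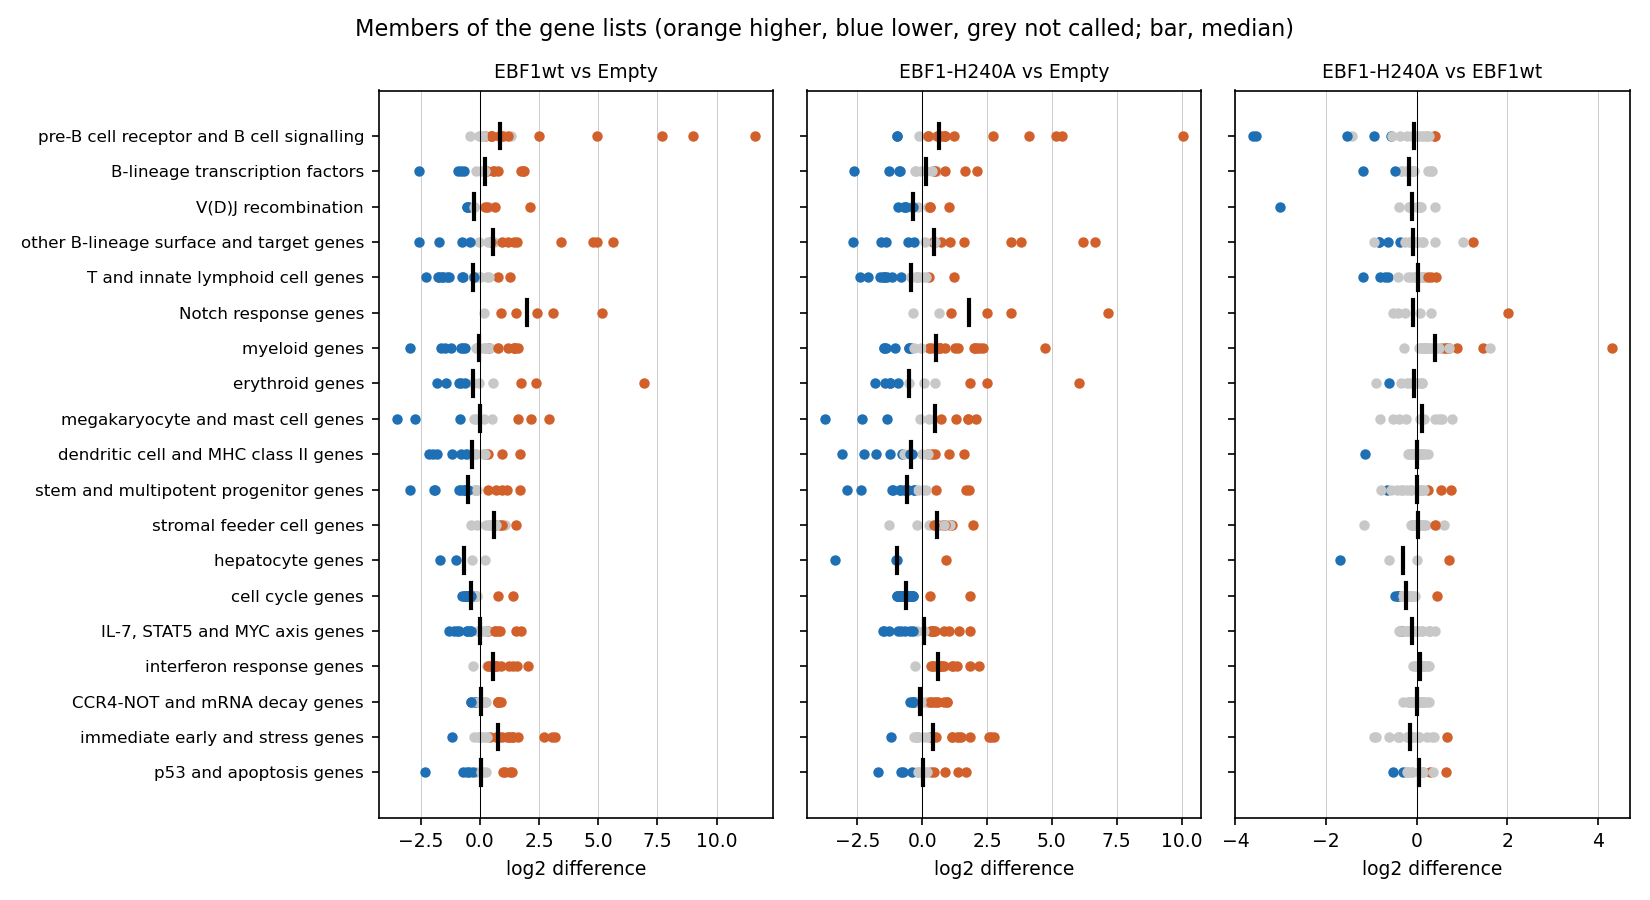
Log2 differences of the measured members of the gene lists (1 point per gene, 1 panel per comparison), with a bar at each list's median, called genes in orange (higher) or blue (lower) and others in grey. The pre-B cell receptor list has medians of 0.86 and 0.65 against Empty, and the myeloid list a median of 0.40 for EBF1-H240A against EBF1wt.

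How far the response to EBF1wt was also seen with EBF1-H240A was then counted. Of the 2798 genes raised by EBF1wt, 2484 (88.8%) were also raised by EBF1-H240A, where independent lists would share 603, and of the 3466 lowered genes 2904 (83.8%) were also lowered, where independent lists would share 798. Without Empty 1 the second count was 1717. The values for independent lists do not allow for the Empty arrays that both comparisons share. Among the raised genes 190 were lower and 265 higher with EBF1-H240A than with EBF1wt, and 2343 were not called different. Of those 190, which include Vpreb1, Igll1, Rag1 and Pou2af1, 115 were still called raised by EBF1-H240A and 75 were not. Among the lowered genes 130 were lower still and 127 higher with EBF1-H240A than with EBF1wt, Mpo being one of the latter. Together 317 EBF1wt-changed genes had a weaker and 395 a stronger response with EBF1-H240A. These counts were 131 and 145 without EBF1wt 1, 158 and 154 without EBF1wt 2 and 232 and 230 without EBF1wt 3. They were 154 and 168 without EBF1-H240A 1 and 168 and 178 without EBF1-H240A 3. With the slide as a block they were 219 and 242, and the 4 groups of 190, 265, 130 and 127 genes became 143, 175, 67 and 76. Leaving out single arrays gave 87 to 180, 104 to 224, 40 to 93 and 44 to 106 for them, the lowest without EBF1wt 1 except for the third, which was lowest without EBF1wt 2. Each of the 4 counts fell by more than 1.5 times without EBF1wt 1, EBF1wt 2, EBF1-H240A 1 or EBF1-H240A 3. The third and the last were also 70 and 63 without Empty 1 and 82 and 62 without Empty 2.

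Over the raised genes the median ratio of the log2 change with EBF1-H240A to that with EBF1wt was 1.07 (interquartile range 0.825 to 1.31), and over the lowered genes 1.05 (0.816 to 1.27). For genes changed at least 2-fold it was 1.02 for the 925 raised and 1.02 for the 457 lowered genes. Across genes, log2 changes with the proteins correlated at r = 0.916, with a simulated value of 0.598 from the shared Empty arrays alone. The covariance was 0.587 against a simulated 0.0369, a difference of 0.550, and 85.5% of genes had the same sign against a simulated 70.5%. In total 5388 genes were called in the same direction for both proteins. The simulations gave a mean of 0.01 such genes, but unchanged groups yield almost no calls, so this is no baseline for the overlap. With EBF1wt set against Empty 1 and EBF1-H240A against Empty 2, which leaves no array in common, r was 0.825 and the covariance 0.555, and with the Empty arrays exchanged r was 0.827.

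**Figure D3:**
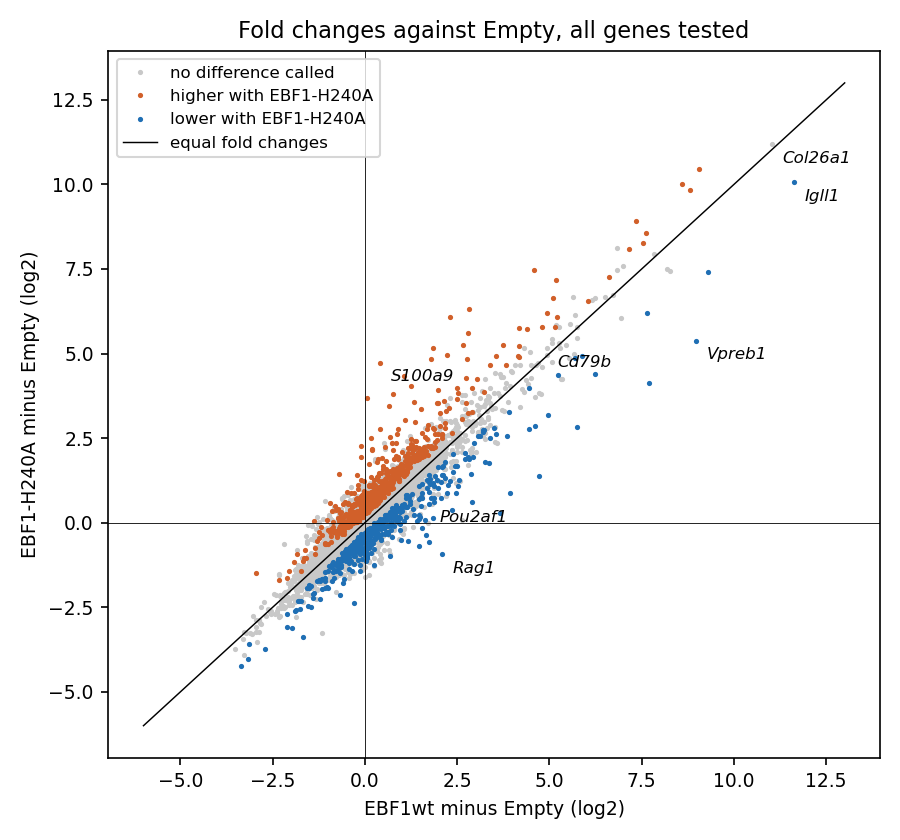
Log2 difference from Empty with EBF1-H240A (y axis) against that with EBF1wt (x axis), 1 point per gene tested, orange where called higher and blue where called lower with EBF1-H240A than with EBF1wt, and a line of equal changes. Vpreb1 lies at 8.98 and 5.38 and Rag1 at 2.10 and -0.92, off the diagonal, while Cd79b lies near it at 4.94 and 5.17.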

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

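In this part, the tests of overall activity, slide, granulocytes, other myeloid cells and feeder cells were chosen only after the results were seen, and the counts of other splits were planned. Genes that moved in opposite directions with the 2 proteins, relative to Empty, and that also differed between them, stood apart as differences between groups. There were 8 such genes raised by EBF1wt and lowered by EBF1-H240A, and 11 lowered by EBF1wt and raised by EBF1-H240A. The difference between the proteins was largest in the first set for Rag1 (-3.02 ± 0.22 on the log2 scale, SE), followed by Clec10a (-1.66 ± 0.09) and Apof (-1.51 ± 0.07). Flt3, the receptor for Flt3 ligand in the medium, rose by 0.34 with EBF1wt and fell by 0.32 with EBF1-H240A, and the others were Sh3tc1, Ldlrad4, Necab3 and the unnamed transcript TC1682312. In the second set Ypel2 differed most (2.15 ± 0.18, from -0.70 with EBF1wt to 1.45 with EBF1-H240A), followed by Btla (1.30 ± 0.08), Tubb6 (1.14 ± 0.07), Ccnb1ip1 (1.14 ± 0.16) and Lyl1 (0.95 ± 0.08). The others were Ccnjl, Pgap1, Tnfrsf21, Lpcat2, Cd93 and Gpr146, and all of these genes are named after their values were seen.

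Of the B-lineage list members, 12 were lower with EBF1-H240A than with EBF1wt: Blk, Cd24a, Fcrla, Igll1, Il2ra, Ly6d, Myb, Pou2af1, Rag1, Tnfrsf13c, Vpreb1 and Vpreb2. They are 18.8% of the 64 measured members of the 4 lists, against 2.72% of all genes (444 of 16310). Another 3 members were higher, and none (0) of the 4 lists was called (camera adjusted p = 0.0532 to 0.218). The share of all genes is a low baseline, because many members of these lists rose with EBF1wt. Of the 2798 genes raised by EBF1wt, 190 were lower with EBF1-H240A. Of those raised at least 2-fold, 5.98% of the 234 undetected with Empty and 13.9% of the other 691 were lower. A lower overall activity of EBF1-H240A is argued against as the whole explanation, because the median ratio of log2 changes over genes raised at least 2-fold by EBF1wt was 1.02. The slide is argued against as the whole explanation of these differences, because with the slide as a block 10 of the 64 members were still called lower and 1 higher. That is 15.6% lower against 1.72% of all genes, again a low baseline. The size of the excess over other genes raised by EBF1wt is therefore not established. Blk (-0.57 ± 0.12 before, -0.55 ± 0.13 with the block) and Fcrla (-0.36 ± 0.07 and -0.37 ± 0.08) then lost their calls, because their SE and adjusted p rose (0.0786 and 0.0738) while the differences moved by less than 1 SE. A dependence of particular genes on the replaced histidine may be a biological explanation and remains a hypothesis. The Ebf1 signal gives no measure of the amounts of the introduced proteins. A lower amount of EBF1-H240A that weakened all raised genes alike is argued against by the same ratio of 1.02. Of the genes raised by EBF1wt, 265 were higher and 190 lower with EBF1-H240A. An effect of different amounts on particular genes stays open, as does the split of signal between the paralogs Vpreb1 and Vpreb2.

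Myeloid genes were higher as a list with EBF1-H240A than with EBF1wt (median 0.40, 8 of 25 members called and 17 not), a call lost with an estimated correlation (adjusted p = 0.321 with an estimated correlation). The slide is argued against, with list medians of 0.28 within slide 1 and 0.52 within slide 2. Mature granulocytes that passed the GFP sort, which should remove cells without the vector, stay open as a candidate source of some members' increase. Of the granulocyte markers S100a8, S100a9, Ngp, Camp and Ltf only 2, S100a8 and S100a9, were well above background on at least 2 EBF1-H240A arrays. Ngp, Camp and Ltf were so on 0 of them, and log2 differences of genes near the floor decide nothing. The mean linear signal rose from 3.13 with EBF1wt to 56.6 with EBF1-H240A for S100a9 and from 3.24 to 11.9 for S100a8. For the lysozyme gene Lyz2 it rose from 18127 to 29891. So small a gain of the markers argues against mature granulocytes as the source of the Lyz2 gain. Monocytes, macrophages or early myeloid progenitors among the sorted cells cannot be told apart from a change within the cells: the members differed widely (interquartile range 0.469), and Itgam, Fcgr3, Cd14, Adgre1 and Cd68, which the studied progenitors may also express, had a median of 0.15. Against Empty the list was not called with either protein: 7 members were higher and 7 lower with EBF1wt (median -0.02), and 16 higher and 7 lower with EBF1-H240A (median 0.54). An effect of the replaced histidine on these genes within the cells stays open and was not tested.

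Stromal genes were higher as a list with both proteins than with Empty (medians 0.59 and 0.58), with 13 and 11 of 19 members not called. Both calls were lost with an estimated correlation (adjusted p = 0.417 and 0.472 with an estimated correlation). With the slide as a block the list was called for both proteins (camera adjusted p = 0.00216 and 0.00502, medians 0.57 and 0.59). These calls rest on the preset correlation and do not decide about the slide. Within slides 1 and 2 the medians were 0.47 and 0.78 with EBF1-H240A, which argues against the slide as the whole explanation there. With EBF1wt they were 0.10 and 0.87, so the size differed between the slides and a part of the slide stays open. Without EBF1wt 3 the EBF1wt median was 0.39. Feeder cells that passed the GFP sort, which should remove cells without the vector, stay open as a candidate source. The members' deviations within groups correlated at 0.297 on average, against a median of -0.00138 and a 95th percentile of 0.0773 in 10000 random lists matched on signal, but interferon response (0.780), myeloid (0.302) and cell cycle genes (0.292) moved together as much or nearly so, and the value is not particular to stromal genes. Pdgfrb rose by 1.54 ± 0.09 with EBF1wt, while the largest increase among Col1a1, Col1a2, Col3a1, Sparc and Fn1, abundant in stromal cells, was 0.65 ± 0.30 (Col3a1, not called). With EBF1-H240A Pdgfrb rose by 1.95 ± 0.09 and Col1a1 by 1.16 ± 0.19. Unequal log2 increases cannot exclude feeder cells as the source of the Pdgfrb increase, because a log2 increase also depends on each gene's signal without them. The log2 signal of Sparc averaged 6.36 with Empty, 6.99 with EBF1wt and 6.92 with EBF1-H240A. A change of these genes in the progenitors themselves also stays open and was not tested.

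The 6 arrays with EBF1 allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 1038 genes and the highest other 20, so that 1 of the 10 splits, the real one, gave as many. Every other split mixes arrays of both proteins in each group, so a real difference widens the spread within its groups and lowers the count. The 20 genes are therefore no baseline for the 1038. For the gene lists the real split gave 2 called lists, the highest other gave 5, and 8 of the 10 splits called at least as many as the real one. The myeloid list was called in 4 of the 9 other splits, with adjusted p = 1.86e-07 for EBF1wt 1, EBF1wt 3 and EBF1-H240A 2 against the rest, below the 2.94e-07 of the real split. The cell cycle list was called in 6 of the 9, with a lowest adjusted p of 6.58e-07 against 7.45e-11 for the real split. The split that follows the slides called 4 lists and, by limma, 0 genes, and with the slide as a block the comparison of the proteins called 2 lists.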

How the results depend on the processing

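In this part, the fits within each slide and the correlation with separate Empty arrays were chosen after seeing the data, and all other alternatives were planned. The signal over background limits what can be said of dim genes, whose changes normexp background correction made smaller (Blk, detected on all arrays, 0.26 with EBF1wt, from 0.82). For the 115 single-gene results, 2069 of 2147 values under the alternatives other than the fits within slides kept the direction and the side of the threshold, 68 lost the call, 3 gained one and 7 reversed an uncalled difference. For the 3 comparisons of Ebf1 these numbers were 54 of 57 kept, 1 gained and 2 reversed, and for the 19 called list results 337 of 361 kept and 24 lost. Most of these genes were chosen for large changes or small adjusted p on these same arrays, so the counts do not describe calls in general. The slide and the scan are the same block but count as 2 alternatives. Of the 1038 genes called for EBF1-H240A vs EBF1wt, 340 were also called with the replicate block, 350 without EBF1wt 1 and 618 with the slide as a block. The fits within slides, which have 1 residual degree of freedom and single arrays in 2 of the 3 groups, are counted apart: of 118 single-gene results, Ebf1 included, 59 kept, 58 lost and 1 reversed within slide 1, and 54 kept, 60 lost and 4 reversed within slide 2. Of the 19 list results 17 kept and 2 lost within slide 1, and 19 kept within slide 2. Except where said otherwise, the cause was not tested.

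Cd79a, EBF1-H240A vs EBF1wt (-0.03), reversed to 0.0312 with normexp background correction, 0.0654 with the slide or the scan as a block, 0.00722 with the series matrix values, 0.16 without EBF1wt 1, 0.00737 without EBF1-H240A 1 and 0.16 within slide 1, with a range of -0.135 to 0.157 without single arrays. Cnot3, EBF1-H240A vs EBF1wt (0.06), reversed to -0.00651 without EBF1wt 2 (up to 0.0995 without other single arrays) and -0.0207 within slide 2. The Ebf1 level, EBF1wt vs Empty (0.03), reversed to -0.34 with the mean over probes, which adds a dim probe, to -0.00792 without Empty 1, the lowest of a range up to 0.0759 without single arrays, and to -0.00194 within slide 2. Within slide 2 the Ebf1 level was -0.0345 for EBF1-H240A vs Empty and -0.0325 for EBF1-H240A vs EBF1wt. Leaving out single arrays gave 0.0951 to 0.236 for EBF1-H240A vs Empty, the highest without EBF1-H240A 3 (adjusted p = 0.0445, with 0.0445 to 0.498 over the alternatives other than the fits within slides). The reversed differences were not called with either sign.

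Genes changed, EBF1-H240A vs EBF1wt (1038), numbered 338 with no filter on dim probes, where 27324 genes were tested, 1751 with a variance trend and robust fit, 646 with the slide or the scan as a block, 652 with the series matrix values, 253 at the stricter threshold, which by construction calls fewer, 365 to 839 without single arrays, and 0 within slide 1 and 0 within slide 2, which hold fewer arrays. Genes changed, EBF1wt vs Empty (6264), numbered 3695 at the stricter threshold (1822 higher and 1873 lower), 4193 without Empty 1 (2203 and 1990) and 133 and 398 within slides 1 and 2. Genes changed, EBF1-H240A vs Empty (7272), numbered 4791 at the stricter threshold and 1101 and 322 within slides. The replicate block gave 360 for EBF1-H240A vs EBF1wt. Other alternatives of these counts stayed within 1.5 times.

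Gene list tests called 1 of the 9 lists with an estimated correlation for EBF1wt vs Empty, and 0 of the 8 lists for EBF1-H240A vs Empty. For EBF1-H240A vs EBF1wt the 2 called lists became 8 with normexp, 4 with probes well above background on all arrays, 6 with the mean over probes, 5 with the series matrix values, 0 with an estimated correlation, 5 within slide 2 and 2 to 5 without single arrays.

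EBF1wt-changed genes weaker with EBF1-H240A (317) numbered 202 with normexp, 121 with no filter, 481 with the trend and robust fit, 0 and 0 within slides and 131 to 286 without single arrays. EBF1wt-changed genes stronger with EBF1-H240A (395) numbered 117 with no filter, 723 with the trend and robust fit, 242 with the slide or scan as a block, 227 with the series matrix values, 0 and 0 within slides and 145 to 317 without single arrays. EBF1wt-raised genes also raised by EBF1-H240A (2484) numbered 122 and 230 within slides. EBF1wt-lowered genes also lowered by EBF1-H240A (2904) numbered 1930 with no filter, 10 and 30 within slides and 1717 to 2664 without single arrays.

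The share of the EBF1wt response seen with EBF1-H240A, raised genes (1.07), was 1.05 with quantile normalization, 1.05 with no filter, 1.09 with probes well above background on all arrays, 1.02 with the series matrix values, 1.02 for genes changed at least 2-fold, 1.02 and 1.01 within slides and 1.03 to 1.07 without single arrays. For lowered genes (1.05) it was 1.07 with quantile normalization, 1.08 when genes were selected on 2 EBF1wt arrays and measured with the third, 1.02 for genes changed at least 2-fold, 1.02 within slide 2 and 1.02 to 1.06 without single arrays. The correlation of fold changes (0.916) was 0.929 with normexp, 0.865 with no filter, 0.892 and 0.877 within slides and 0.894 to 0.920 without single arrays. It was 0.825 with EBF1wt against Empty 1 and EBF1-H240A against Empty 2, and 0.827 with the Empty arrays exchanged.

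Over the alternatives other than the fits within slides, the adjusted p of genes whose calls changed ranged as follows. For EBF1wt vs Empty it was 0.0154 to 0.392 for Cd79a, 0.00117 to 0.0895 for Blk and 0.00127 to 0.106 for Cnot3. For EBF1-H240A vs Empty it was 0.0136 to 0.347 for Cd79a, 0.0031 to 0.156 for Cnot3, 0.0122 to 0.258 for Pou2af1 and 4.44e-06 to 0.0624 for Il20ra. For EBF1-H240A vs EBF1wt it was 0.0178 to 0.898 for Blk, 0.00459 to 0.232 for Pou2af1, 0.00156 to 0.0779 for Ccnd1, 0.00164 to 0.0895 for Mcm5, 0.000175 to 0.0533 for Cebpb, 0.000206 to 0.0582 for S100a9, 5.12e-07 to 0.0597 for Srd5a2, 1.26e-12 to 0.0526 for Kcne1 and 0.00127 to 0.0545 for Klra2. Lists whose calls changed with more than the correlation were stem and progenitor genes, EBF1wt vs Empty (0.0039 to 0.201), other B-lineage genes, EBF1wt vs Empty (0.000662 to 0.17), and Notch response genes, EBF1-H240A vs Empty (0.000124 to 0.258). Within slide 1 the stem and progenitor list (0.159) and the stromal list (0.129), both EBF1wt vs Empty, were not called, in a fit of 1 array against 1 whose spread comes from EBF1-H240A. Within slides the adjusted p reached values outside these ranges, for example 0.136 for Blk within slide 1 and 0.262 for Cnot3 within slide 2, both EBF1wt vs Empty.

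Whether the replicate numbers pair the arrays could not be decided. Same-numbered arrays had deviations from their group means that correlated at -0.33 to 0.19, and not every array correlated best with its own number. Deviations from a group mean cancel out within the group, so the values of the Empty arrays mirror each other. The effect of the slide was not separated from that of the number. These correlations therefore neither show nor exclude pairing. With the replicate block 4810 genes were called for EBF1wt vs Empty and 5925 for EBF1-H240A vs Empty. The replicate block gave 141 genes weaker and 121 stronger with EBF1-H240A, and a raised share of 1.05.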

Other observations

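In this part, the tests of matched draws, of distant pairs and of the comparisons with Empty were added after the results were seen, while the tests of silent genes and of neighbouring genes were chosen before. Several lists held single members with large changes against Empty although the list was not called. Among mRNA decay genes, the deadenylase partner genes Tob1 (0.78 ± 0.09 with EBF1wt, 0.62 with EBF1-H240A) and Tob2 (0.90 ± 0.10 and 0.94) and the deadenylase gene Pan2 (0.75 ± 0.10 and 0.98) rose, while Cnot1 (-0.28 and -0.29) and the helicase gene Ddx6 (-0.39 ± 0.06 and -0.36) fell slightly. On the interleukin 7 axis the feedback genes Cish (1.74 ± 0.07 and 1.41) and Socs3 (1.54 ± 0.11 and 1.84) rose, while Socs1 (-0.96 and -0.95), Pim2 (-0.86 and -1.26) and the survival gene Bcl2 (-1.32 ± 0.08 and -1.51) fell. Among p53 and apoptosis genes Fas (1.34 ± 0.10 and 1.70) and Cdkn1a (1.05 and 0.86) rose. All these members were chosen after their values were seen.

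Among dendritic cell and MHC class II genes, Itgax (-2.16 ± 0.18 and -2.26 ± 0.18), Batf3 (-1.79 ± 0.15 and -1.78) and the MHC class II regulator gene Ciita (-1.18 ± 0.20 and -1.22) fell with both proteins, while H2-DMb1 rose (1.70 ± 0.17 and 1.62). Among myeloid genes, Itgam (-1.66 ± 0.22 and -1.45), Fcgr3 (-1.45 ± 0.14 and -1.39) and Cd14 (-1.21 and -1.06) fell relative to Empty with both proteins, whereas Csf2rb (1.44 and 2.10) rose. Among erythroid genes Nfe2 (2.39 ± 0.10 and 2.51) and the carbonic anhydrase gene Car2 (1.75 ± 0.07 and 1.85) rose, and the transferrin receptor gene Tfrc fell (-0.64 and -1.25). The B-lineage transcription factor genes Lef1 (-2.55 ± 0.14 and -2.61 ± 0.14) and Sox4 (-0.90 and -1.26) fell with both proteins.

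The first hypothesis was that genes silent in the Empty cells depend more on the replaced histidine than genes already expressed there. Among genes raised at least 2-fold by EBF1wt, 5.98% of the 234 not well above background on either Empty array were lower with EBF1-H240A than with EBF1wt, against 13.9% of the other 691 (Fisher's exact test, two-sided, p = 0.000972). The difference ran opposite to the hypothesis. Silent genes also had the larger median SE (0.254 against 0.114), so part of it may come from lower power for dim genes. The shares higher with EBF1-H240A were 12.4% and 16.4% (Fisher's exact test, p = 0.172). Both tests treat genes as independent, although all were measured on the same arrays, so their p-values do not measure the spread between samples.

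The second hypothesis was that genes that differ between the proteins lie next to each other on chromosomes. The 13659 genes were placed by their order in the reference, and adjacent pairs whose symbols shared a stem (the letters before the number) were left out. Of the 12783 pairs kept, 80 were called in the same direction, where 10000 random draws gave a median of 28 and a 95th percentile of 37 (permutation p = 0.0001, the smallest that this number of draws can give). Draws matched on mean signal gave 28 and 37 as well. With only pairs whose probes lie more than 10000 bases apart and whose symbols differ in their first 3 letters, 64 of 10445 pairs remained against a random median of 23 and a 95th percentile of 31. Over the 12783 pairs, without the limits on distance and on the first 3 letters, genes changed at least 2-fold against Empty were also counted. They gave 147 pairs against 57 in draws matched on signal for EBF1wt and 183 against 78 for EBF1-H240A. Examples, chosen after their values were seen, were Igll1 and Vpreb1, Iftap (-1.55) and Rag1 (-3.02), Lynx1 (-0.76) and Ly6d (-0.82), Mc1r (-2.29) and Tubb3 (-2.02), and Tnf (0.53) and Lta (0.61). The 80 pairs may reflect regional effects of EBF1. The draws, however, also remove any co-expression that neighbouring genes have without such effects, so they cannot tell these apart. Overlapping transcripts and probes that detect a neighbour's transcript were not excluded for each pair.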
